A study of Mus musculus with 43 samples.

How the data were processed

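RNA sequencing read counts were analysed for 43 lung libraries of mice in 3 groups. The groups were control mice given vehicle (n = 10), bleomycin mice given vehicle (n = 16) and bleomycin mice given nintedanib (n = 17). The labels call the vehicle of the bleomycin mice that of nintedanib and do not name the vehicle of the control mice. A difference in vehicle cannot be told apart from bleomycin in the comparisons with control mice. Bleomycin is an antibiotic that breaks DNA and is used in rodents to induce lung fibrosis. Nintedanib is an inhibitor of the VEGF, FGF and PDGF receptor tyrosine kinases that is used to treat idiopathic pulmonary fibrosis. Per the labels' protocols, RNA came from the inferior lobe, polyA RNA was made into directional libraries, and reads were single-end. The labels give no dose, route, day, sex, strain or cage. The library names fall into 3 number series, called A, B and C here, with 33, 4 and 6 libraries; the labels do not say what the series mean. Each library is taken as 1 mouse, since the labels describe separate samples; no label states more on this, so p-values measure the spread between these samples.

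The authors deposited 1 table of whole-number counts per gene with 1 column per library. Per the submitters' processing notes, STAR 2.7.0f, R 3.6.0 and the GRCm38 genome build were used, without a role for each. The counting tool, its strand setting, the annotation release and any filter are not given in the sources used here. The table held 21938 genes, all protein-coding in the GENCODE annotation of GRCm38 used here for symbols and coordinates, and each gene identifier matched a symbol. Mitochondrially encoded genes were absent from the table. Reads of near-identical genes (Hba-a1 and Hba-a2, Hbb-bt, Saa3, Cyp2a5, Tpsb2, Mcpt4, and the Oas and Hspa1b families) could have been divided between copies or lost, and their values are uncertain. Overlapping and antisense genes cannot be told apart where the strand setting is unknown.

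Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 14836 genes with 99.96% of counts. Depth was 13138281 to 19111457 counts per library, and the median biological coefficient of variation of a gene was 13.6%. The main test was edgeR's quasi-likelihood F test, two-sided, with TMM factors, robust dispersion and 1 coefficient per group over all 43 libraries. The 3 comparisons share 1 estimate of spread. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Per-library values are log2 CPM (counts scaled to library size) with TMM factors and a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

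The groups, the tests, 54 gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Of 895 distinct genes in the lists, 861 were found in the table and 822 were tested, and 53 lists had at least 3 tested members. Lists were tested with camera from limma, which compares a list with all other genes, at its preset correlation between genes of 0.01, and again with the correlation estimated from the data. The fry test asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. P-values of lists were adjusted over the 53 lists. For each list the count of called members is given over all genes and adjusted over the list alone.

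A list score per mouse is the mean log2 CPM of the tested members. Scores of the bleomycin groups were compared by a two-sided permutation test with 100000 resamples, with 95% percentile bootstrap intervals from 10000 resamples of mice. Spread between mice was compared by permuting absolute deviations from the group median. The bleomycin change under nintedanib was measured as a slope across genes of nintedanib minus vehicle on vehicle minus control. The 16 vehicle libraries were split into 2 sets of 8, 50 times, so that no library stood on both sides, and genes and x values came from the first set. A slope of 0 means no shift and a slope of -1 means a full return to control.

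The named genes of a comparison are the 8 largest rises and the 8 largest falls among genes past the threshold with an average log2 CPM of at least 2, leaving out unnamed gene models. To these come up to 4 members past the threshold of each described list (or up to 2 with the smallest p where none passed) and 19 genes given in every comparison.

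The test was checked on simulated counts drawn from the real means, spreads and library sizes, with known changes. For nintedanib against vehicle, 61.2% of genes changed 1.25-fold and 95.5% of genes changed 1.5-fold were recovered, and 4.42% of calls were false. For bleomycin against control the recovery was 40.3% at 1.25-fold and 76.1% at 1.5-fold. For nintedanib against control it was 56.7% and 88.1%. A simulated rise of the cell cycle list was found by camera with 0 of 52 other lists called, and a simulated slope of -0.3 was estimated as -0.281. Genes were drawn independently and with the same spread in each group. The check therefore says nothing on genes that vary together, on groups that differ in spread, or on camera's preset correlation. The alternatives tried were DESeq2, voom with sample quality weights, other scalings, other count filters, fits of 2 groups alone, the library series as a covariate or series A alone, 2 surrogate variables, the 20 most abundant genes left out, and each bleomycin library left out in turn. Fits without the libraries with at least 1 CPM of Adipoq, fits with fat and airway scores as covariates, and a bleomycin axis score were chosen after seeing the data.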

Results

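Gene counts were measured in the inferior lung lobe of 43 mice. Control mice given vehicle gave 10 libraries, bleomycin mice given vehicle gave 16 and bleomycin mice given nintedanib gave 17. Library totals ran from 13138281 to 17812995 counts in control mice, from 13175246 to 19111457 in vehicle mice and from 13324549 to 18723538 in nintedanib mice. The 10 most abundant genes took 4.68% to 9.77% of a library's counts. No library pair of the same group agreed within sampling noise, since the smallest chi-square per degree of freedom among 301 pairs was 5.36.

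The first principal component of log2 CPM held 43.4% of the variance and separated bleomycin from control lungs, and the second held 10.6%. Along the first 2 components the nintedanib and vehicle groups overlapped. On the third, with 6.09% of the variance, they differed in mean, with 12.1 (lowest -3.3) under nintedanib and -5.8 (highest 8.0) under vehicle. Mice of both groups lay in the shared range.

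**Figure D1:**
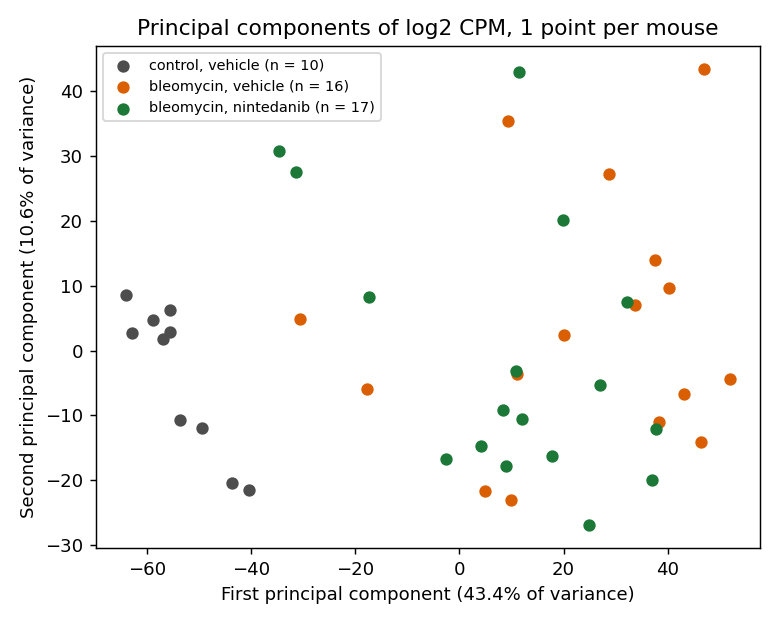
Each point is 1 mouse; the x axis is the first principal component of log2 CPM (43.4% of variance) and the y axis the second (10.6%), in arbitrary units, with the 10 control, 16 bleomycin vehicle and 17 bleomycin nintedanib mice in different colours. Control mice lie apart from bleomycin mice on the x axis, and the bleomycin groups overlap.

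The first comparison, bleomycin vehicle against control vehicle, asked how injured lungs differed from control lungs, whose vehicle may not be the same. Bleomycin lungs carried a fibrosis programme of collagens, matrix proteins and crosslinking enzymes. Markers of profibrotic macrophages, transitional alveolar epithelium, dividing cells, and p53 targets and senescence were also higher. Most markers of capillary endothelium, alveolar fibroblasts and B cells were lower, and so were airway genes in the libraries as a whole. With an estimated correlation only the macrophage, p53 and transitional epithelium lists kept their calls, and without the libraries holding Adipoq the airway lists lost theirs (adjusted p = 0.20 for club and 0.37 for ciliated genes). Among genes past the threshold with an average log2 CPM of at least 2, to which the word largest refers throughout, the largest rises were those of Grem1, a BMP antagonist, Thbs4, a matrix protein, Slc26a4, an anion exchanger, and the acute-phase gene Saa3. Chl1, Sprr1a, Spp1 and Mmp12 followed.

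By edgeR's quasi-likelihood test, 8585 of 14836 genes changed (Benjamini-Hochberg adjusted p under 0.05), 4381 upward and 4204 downward, and 1493 of them at least 2-fold. The majority turned with the scaling, to 4229 upward and 4373 downward with RLE factors and 3736 and 4882 with library totals. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, GRCm38), had a mean log2 CPM of 6.10 ± 0.47 (SD, n = 10) in control mice and 10.51 ± 0.75 (n = 16) in vehicle mice. Its log2 fold change was 4.50 ± 0.31 (SE, adjusted p = 2e-15), and 16 of 16 vehicle mice lay above the control median. Grem1 rose by 5.81 ± 0.61 on the log2 scale (adjusted p = 1.8e-10) and Thbs4 by 5.30 ± 0.69 (adjusted p = 2.1e-08). Slc26a4 had a log2 fold change of 5.03, Saa3 of 4.82, Chl1 of 4.66 and Sprr1a of 4.62.

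All 18 collagens of the fixed list rose (18 adjusted over the list alone), with a median log2 fold change of 1.41 (camera adjusted p = 2.5e-06 and adjusted p = 0.34 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) rose by 1.96 ± 0.34 and Col3a1 by 1.95 ± 0.20, each in 16 of 16 mice, and Col11a1 by 4.67 and Col24a1 by 3.57. Of 25 matrix glycoproteins 20 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 1.4e-05 and adjusted p = 0.34 with an estimated correlation), led by Spp1, Tnc (4.11), Thbs2 (2.93) and Eln (2.91), and Fn1 rose by 2.56. Of 26 crosslinking enzymes, proteases and inhibitors 20 rose and 1 fell (20 and 3 adjusted over the list alone, camera adjusted p = 1.7e-08 and adjusted p = 0.33 with an estimated correlation), with Mmp12 at 4.13, Adamts4 at 3.63, P4ha3 at 3.62 and Timp1 at 3.44. Of 20 TGF-beta genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.4e-05 and adjusted p = 0.34 with an estimated correlation). The contractile gene Acta2 had a log2 fold change of 0.05 (adjusted p = 0.84) and Postn of 0.02 (adjusted p = 0.90), and of 18 activated fibroblast genes 10 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.52 with an estimated correlation and 0.070 without the Adipoq libraries).

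The calls of 3 lists held with an estimated correlation. Of 24 genes of monocyte-derived and profibrotic macrophages 19 rose and none fell (19 adjusted over the list alone, camera adjusted p = 1.1e-19 and adjusted p = 0.0094 with an estimated correlation), led by Spp1, Mmp12, Gpnmb (3.96) and Trem2 (3.82). Of 22 p53 target and senescence genes 17 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0015 with an estimated correlation). Ckap2 was in front, with Gdf15 at 2.51, Cdkn2a at 2.34 and Cdkn1a at 2.19 ± 0.12. Of 19 genes of the transitional alveolar epithelium 17 rose and none fell (17 adjusted over the list alone and adjusted p = 0.046 with an estimated correlation), with Sprr1a, Lcn2 (2.99), Cldn4 (2.54) and Areg (2.47) in front and Krt8 at 1.02. All 27 cell cycle genes rose (27 adjusted over the list alone, camera adjusted p = 3.7e-10 and adjusted p = 0.34 with an estimated correlation), with Ccnb1 at 2.85 and Mki67 at 2.03 ± 0.30 in 15 of 16 mice. Of 22 alveolar type 2 genes 13 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0030 and adjusted p = 0.52 with an estimated correlation), with Scd1 at 1.18, Il33 at 1.11, Sftpd at 1.03 and Muc1 at 1.02. Sftpc of these cells had a log2 fold change of 0.28 (adjusted p = 0.064) and Ager of alveolar type 1 cells of 0.23 (adjusted p = 0.056).

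Of 22 pan-endothelial genes 19 fell (20 adjusted over the list alone, camera adjusted p = 2.5e-11 and adjusted p = 0.33 with an estimated correlation), with a median of -0.78. Kdr, the main VEGF receptor, had a log2 fold change of -1.05 ± 0.12 (lower in 16 of 16 mice) and Flt1 of -0.68. Of 17 general capillary genes 13 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 1.8e-05 and adjusted p = 0.33 with an estimated correlation), with Cd300lg at -1.65 and Bmp6 at -1.55. Of 15 alveolar fibroblast genes 12 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.4e-05 and adjusted p = 0.34 with an estimated correlation), with Slc7a10 at -2.01, Inmt at -1.73, Fgfr4 at -1.19 and Tcf21 at -1.04. Of 15 B cell genes 14 fell (14 adjusted over the list alone, camera adjusted p = 1.8e-05 and adjusted p = 0.40 with an estimated correlation), and Pax5 was at -1.53.

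The 8 largest falls belonged to genes of fat (Pck1, Car3, Cfd, Adipoq, Plin1) and of large-airway mucosa (Reg3g, Bpifb1, Bpifa1). Adipoq (chromosome 16, 23146536 to 23158028), an adipocyte gene, reached at least 1 CPM in 8 of 10 control libraries, 0 of 16 vehicle libraries and 5 of 17 nintedanib libraries. Its mean was 21.3 ± 35.4 CPM (SD, n = 10) in control mice, and in vehicle mice it had 10 counts over 16 libraries. Bpifa1 had a mean of 274 ± 371 CPM in control mice, 4.63 ± 6.07 in vehicle mice and 312 ± 672 in nintedanib mice. Of 17 club and secretory genes 13 fell (13 adjusted over the list alone, camera adjusted p = 3e-04 and adjusted p = 0.39 with an estimated correlation), and of 19 ciliated genes 18 fell (18 adjusted over the list alone, camera adjusted p = 0.00045 and adjusted p = 0.50 with an estimated correlation). All 11 adipose genes fell (11 adjusted over the list alone, camera adjusted p = 0.0020 and adjusted p = 0.44 with an estimated correlation). Without the libraries with at least 1 CPM of Adipoq, an alternative chosen after seeing the data that leaves 2 control libraries, 3654 genes were called, 3519 of them among the 8585. There the club (adjusted p = 0.20), ciliated (adjusted p = 0.37) and adipose (adjusted p = 0.70) lists were no longer called. Other lists that lost their call there were activated fibroblasts (adjusted p = 0.070), smooth muscle (adjusted p = 0.13), lymphatic (adjusted p = 0.13), dendritic (adjusted p = 0.36), interferon (adjusted p = 0.93) and glucocorticoid (adjusted p = 0.068) genes.

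**Figure D2:**
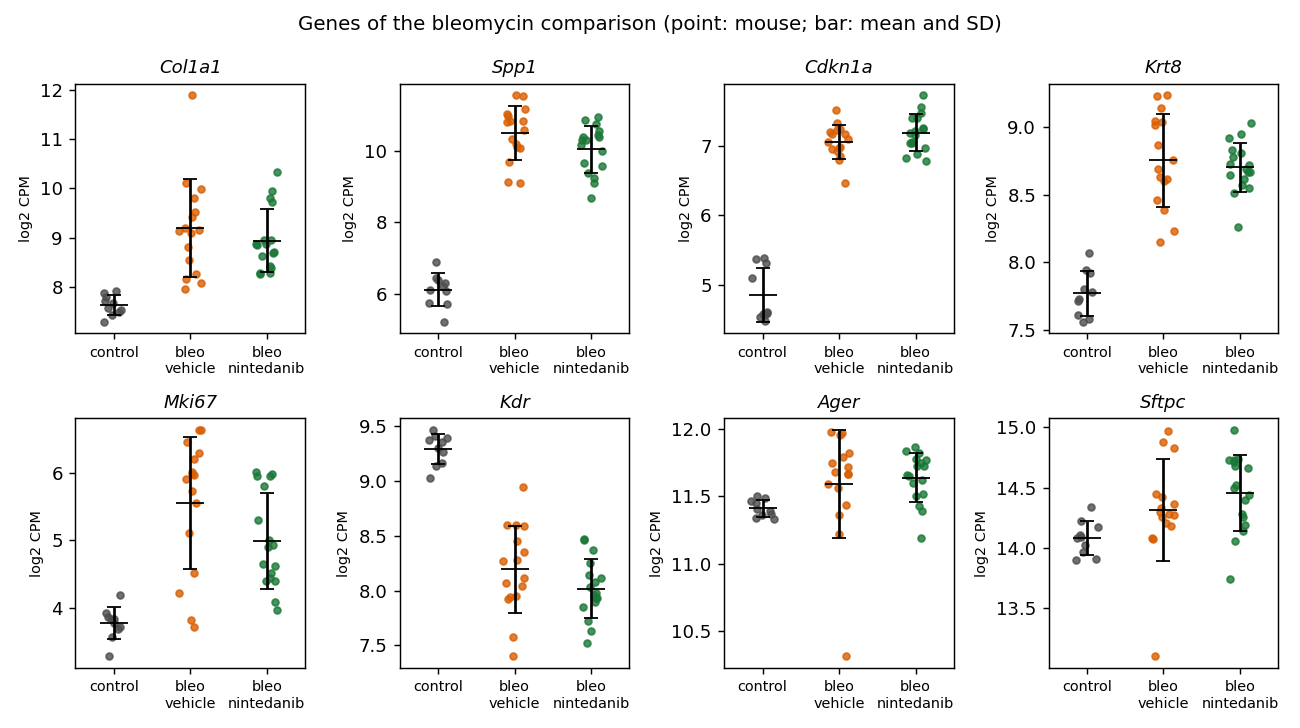
Each panel gives log2 CPM of 1 gene, each point 1 mouse, and black bars the group mean and SD for control (n = 10), bleomycin vehicle (n = 16) and bleomycin nintedanib (n = 17). Spp1 lies at 6.10 in control mice, 10.51 in vehicle mice and 10.05 in nintedanib mice, and Kdr at 9.29, 8.19 and 8.02.

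The second comparison, nintedanib against vehicle in bleomycin mice, asked what the drug changed in injured lungs. Part of the VEGF-responsive genes (6 of 22), of the genes of ERK feedback and output (3 of 18) and of the lymphatic genes (4 of 9, with Lyve1 higher) fell under nintedanib. These list calls were lost with an estimated correlation (adjusted p = 0.099, 0.099 and 0.26). The pattern recognition gene Ptx3 had the largest fall, followed by Apold1, an endothelial early response gene, Prox1, the lymphatic master regulator, and Nos2. Of the dendritic cell genes 11 of 21 fell, while 6 of 19 genes of the unfolded protein response and 7 of 12 of red blood cells and platelets rose. These calls too were lost with an estimated correlation (adjusted p = 0.17, 0.099 and 0.17). Collagens, matrix proteins, transitional epithelium and profibrotic macrophage genes did not pass the test as lists, but with 2 surrogate variables the matrix list passed as higher (adjusted p = 0.018). The TGF-beta list was called lower (adjusted p = 0.049) and the alveolar fibroblast list higher (adjusted p = 0.00034), neither with an estimated correlation (adjusted p = 0.70 and 0.46).

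By edgeR's quasi-likelihood test 1084 of 14836 genes changed, 476 upward and 608 downward, 71 of them at least 2-fold. With only the 2 groups in the fit, without the control mice, 640 were called. The majority turned to 746 upward and 562 downward with 2 surrogate variables, to 510 and 503 with fat and airway covariates and to 454 and 439 with the axis covariate. Ptx3 (chromosome 3, 66219910 to 66225805) had a mean log2 CPM of 2.87 ± 0.78 (SD, n = 16) under vehicle, 0.33 ± 1.02 (n = 17) under nintedanib and 0.48 ± 0.52 (n = 10) in control mice. Its log2 fold change between bleomycin groups was -2.43 ± 0.30 (SE, adjusted p = 1.1e-06), and 17 of 17 nintedanib mice lay below the vehicle median. Apold1 had a log2 fold change of -1.17 ± 0.17 (adjusted p = 2.8e-05, 17 of 17 mice), Prox1 of -1.08 ± 0.19 (adjusted p = 0.00042, 17 of 17 mice) and Nos2 of -1.04 ± 0.18 (adjusted p = 0.00047, 16 of 17 mice). Egr1 (-1.03), Egr3 (-1.01), Spry4 (-1.01) and the dendritic cell gene Fscn1 (-1.01) completed the 8 largest falls. The fixed list of immediate early and dissociation stress genes, which holds genes of this kind, was also called lower (camera adjusted p = 0.049 and adjusted p = 0.70 with an estimated correlation), with 4 of 20 members lower and 3 higher (6 and 4 adjusted over the list alone), and its score differed by -0.22 (-0.42 to -0.03, adjusted permutation p = 0.11).

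Of 22 VEGF-responsive genes 6 fell and none rose (7 adjusted over the list alone, camera adjusted p = 6e-05 and adjusted p = 0.099 with an estimated correlation). Plxnd1 (chromosome 6, 115954811 to 115995005) had a log2 fold change of -0.46 ± 0.06 (adjusted p = 1.1e-06) and Apln of -0.72 ± 0.13 (adjusted p = 0.00079), each lower in 17 of 17 mice, with Unc5b at -0.61 and Pgf at -0.50. Of 18 genes of ERK feedback and output 3 fell (5 adjusted over the list alone, camera adjusted p = 6e-05 and adjusted p = 0.099 with an estimated correlation): Spry4 (chromosome 18, 38586247 to 38601415; -1.01 ± 0.14, adjusted p = 7.9e-06, 17 of 17 mice), Egr1 and Dusp6 (-0.37). Of 9 lymphatic genes Prox1, Reln (-0.53), Mmrn1 (-0.48) and Flt4 (-0.47) fell and Lyve1 (0.57) rose (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0018 and adjusted p = 0.26 with an estimated correlation). Of 22 pan-endothelial genes 2 fell, Emcn (-0.31) and Ecscr (-0.25), with 3 adjusted over the list alone (camera adjusted p = 0.65). The list's median was 0.02, against a test direction of lower. With 2 surrogate variables the pan-endothelial list (adjusted p = 0.030) and the aerocyte capillary list (adjusted p = 0.014) were called lower.

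Among 14 kinases that nintedanib inhibits, Flt3 (-0.57), Flt4, Pdgfrb (-0.40) and Lyn (-0.22) fell and Pdgfra (0.43) rose (4 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.028 and adjusted p = 0.26 with an estimated correlation). Camera no longer called this list in series A (adjusted p = 0.058) and without the Adipoq libraries (adjusted p = 0.10), and called it with 2 surrogate variables (adjusted p = 0.0056), as did fry in all libraries (adjusted p = 0.0065). Its score differed by -0.108 (adjusted permutation p = 0.051), by -0.136 in series A and by -0.103 without the Adipoq libraries. As a median over members the score did not pass (adjusted permutation p = 0.24), and as mean z scores it did (adjusted permutation p = 0.012). Kdr had a log2 fold change of -0.20 (adjusted p = 0.22), Flt1 of -0.05 (adjusted p = 0.77) and Fgfr1 of -0.12 (adjusted p = 0.38). Of 21 dendritic cell and antigen presentation genes 11 fell (19 adjusted over the list alone, camera adjusted p = 3e-11 and adjusted p = 0.17 with an estimated correlation), with Fscn1, Flt3, Ccr7 (-0.54) and Batf3 (-0.47) in front. Of 27 cell cycle genes 4 fell, Ccnb2 (-0.75), Bub1b (-0.66), Aurka (-0.62) and Ccne2 (-0.47), and 27 adjusted over the list alone (camera adjusted p = 3.2e-11 and adjusted p = 0.46 with an estimated correlation), and Mki67 was at -0.64 (adjusted p = 0.085). Of 19 unfolded protein response genes 6 rose (10 adjusted over the list alone, camera adjusted p = 1.3e-06 and adjusted p = 0.099 with an estimated correlation), with Herpud1 at 0.28, Hspa5 and Asns at 0.25 and Dnajb9 at 0.24. Of 12 erythrocyte and platelet genes 7 rose (10 adjusted over the list alone, camera adjusted p = 4.9e-10 and adjusted p = 0.17 with an estimated correlation), with Slc4a1 at 1.04 and Hbb-bt and Ppbp at 0.74.

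None of the 18 collagens passed over all genes or adjusted over the list alone; the list's median log2 fold change was -0.30 (camera adjusted p = 0.064), with Col1a1 at -0.52 ± 0.27 (adjusted p = 0.23) and Col3a1 at -0.23 (adjusted p = 0.38). With 2 surrogate variables the direction of the collagen list turned to higher (adjusted p = 0.060), and the matrix (adjusted p = 0.018) and crosslinking (adjusted p = 0.0012) lists were called higher. Of 20 TGF-beta genes Tgfb1 (-0.24) and Tgfb2 (-0.22) fell (2 adjusted over the list alone). The list's call was lost in series A (adjusted p = 0.27), with 2 surrogate variables (adjusted p = 0.99) and without the Adipoq libraries (adjusted p = 0.17). Of 15 alveolar fibroblast genes Gpc3 (0.40) and Macf1 (0.19) rose and Scn7a (-0.33) fell (the same adjusted over the list alone). This list was still called in series A (adjusted p = 0.0019), with 2 surrogate variables (adjusted p = 0.0036) and without the Adipoq libraries (adjusted p = 0.00046). Of 25 matrix genes only Ogn (0.62) passed (1 adjusted over the list alone, camera adjusted p = 0.46), with Fn1 at -0.25, Tnc at -0.48 and, of the crosslinking list, Timp1 at -0.10. Of 18 activated fibroblast genes only Pdgfrb passed (1 adjusted over the list alone, camera adjusted p = 0.28), and of 24 profibrotic macrophage genes 1 passed (0 adjusted over the list alone, camera adjusted p = 0.15), with Spp1 at -0.49 (adjusted p = 0.14). Of 22 p53 target and senescence genes Plk2 (-0.55) passed (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.36), with Cdkn1a at 0.13 (adjusted p = 0.41). None of the 19 transitional epithelium genes passed over all genes (3 lower adjusted over the list alone, camera adjusted p = 0.20), with Krt8 at -0.08. Acta2 was at 0.23 (adjusted p = 0.41).

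The 8 largest rises under nintedanib were those of fat and airway genes that few libraries held: Pck1, Cfd, Car3 and Adipoq of fat and Reg3g, Bpifa1, Bpifb1 and Krt15 of airway mucosa. Adipoq had a median of 0.0625 CPM under nintedanib and a highest value of 57.4 CPM. Bpifa1 had a median of 1.47 CPM and a highest value of 2360 CPM. Of 17 club and secretory genes 5 rose (7 adjusted over the list alone, camera adjusted p = 0.00034 and adjusted p = 0.46 with an estimated correlation), and of 11 adipose genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.0098 and adjusted p = 0.70 with an estimated correlation). Without the Adipoq libraries neither list was called (adjusted p = 0.68 and 0.48). Of 14 smooth muscle genes 4 rose, Cnn1 (0.99), Myh11 (0.50), Lmod1 (0.42) and Synpo2 (0.34), with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00036 and adjusted p = 0.46 with an estimated correlation), and the list was not called without the Adipoq libraries (adjusted p = 0.064). Camera called 23 lists, 0 of them with an estimated correlation (7 at an unadjusted p under 0.05), and fry called 9. Without the libraries with at least 1 CPM of Adipoq 525 genes were called, 445 of them among the 1084. Among the genes lost were Pdgfra, Pdgfrb, Egr1, Dusp6, Flt3, Aurka and Slc4a1. With library totals alone as the scaling the split was 369 upward and 813 downward, and without nintedanib mouse 1 the count was 696.

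**Figure D3:**
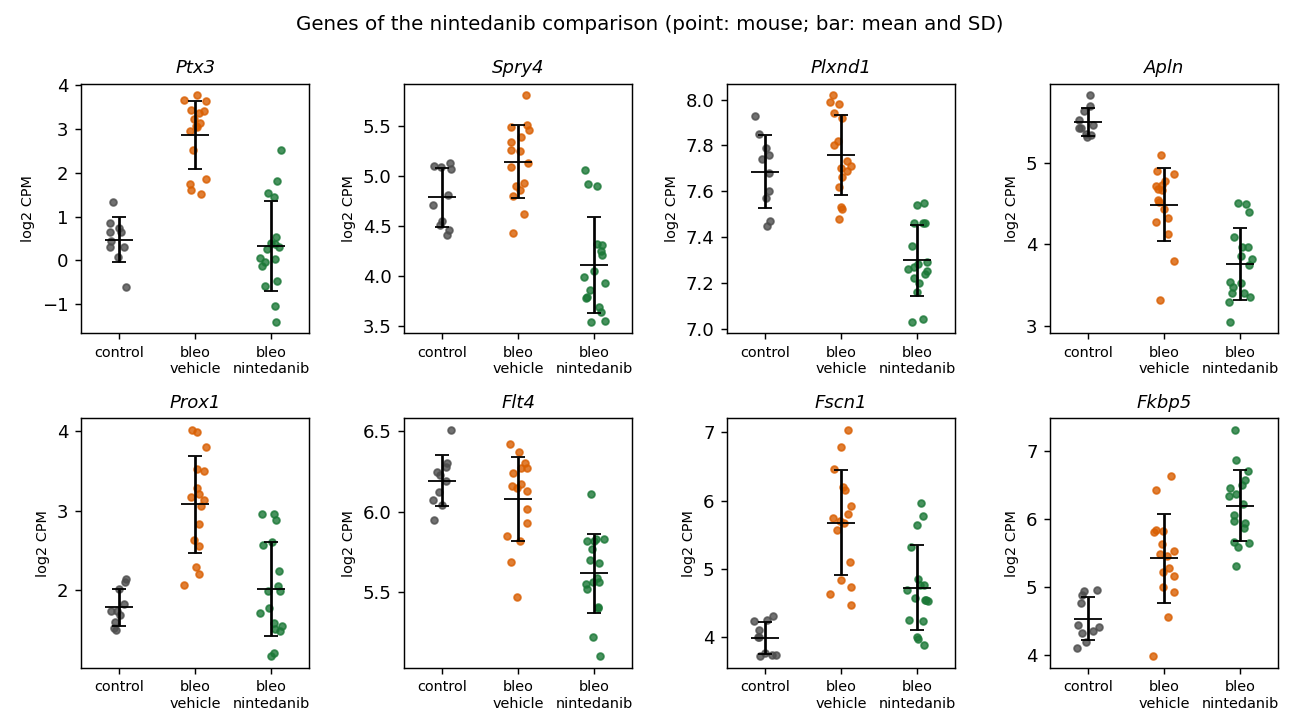
Each panel gives log2 CPM of 1 gene, each point 1 mouse, and black bars the group mean and SD for control (n = 10), bleomycin vehicle (n = 16) and bleomycin nintedanib (n = 17). Ptx3 lies at 0.48 in control mice, 2.87 under vehicle and 0.33 under nintedanib, and Spry4 at 4.78, 5.14 and 4.10.

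**Figure D4:**
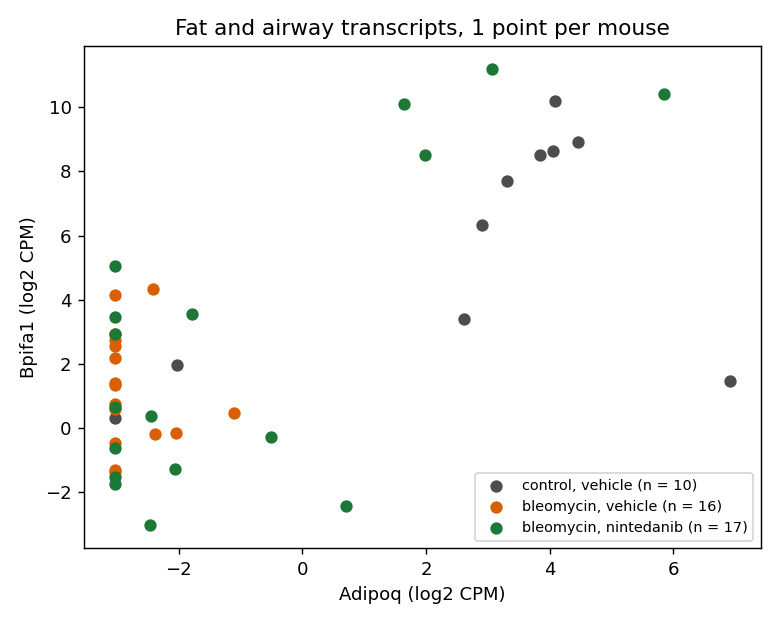
Each point is 1 mouse; the x axis is log2 CPM of Adipoq (fat) and the y axis log2 CPM of Bpifa1 (airway mucosa), with the 10 control, 16 bleomycin vehicle and 17 bleomycin nintedanib mice in different colours. Adipoq reached at least 1 CPM in 8 control, 0 vehicle and 5 nintedanib mice.

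List scores per mouse gave a readout with 1 value per animal. Of 53 lists, 10 differed between nintedanib and vehicle after Benjamini-Hochberg adjustment, 6 higher and 4 lower. ERK feedback genes had a difference of mean log2 CPM of -0.27 (95% interval -0.37 to -0.17, adjusted permutation p = 0.0021; 16 of 17 mice below the vehicle median), and dendritic cell genes of -0.42 (-0.64 to -0.20, adjusted permutation p = 0.010; 15 of 17). Lymphatic genes had a difference of -0.25 (adjusted permutation p = 0.042; 15 of 17) and VEGF-responsive genes of -0.15 (adjusted permutation p = 0.042; 14 of 17). Erythrocyte genes were higher by 0.66 (0.35 to 0.95, adjusted permutation p = 0.0034; 17 of 17) and unfolded protein response genes by 0.16 (0.09 to 0.22, adjusted permutation p = 0.0029; 16 of 17). Vehicle minus control was 0.28 for ERK feedback, 0.42 for dendritic cell, 0.44 for lymphatic and -0.48 for VEGF-responsive genes. It was -1.16 for erythrocyte and 0.19 for unfolded protein response genes. Smooth muscle and drug metabolism genes were each higher by 0.36, glucocorticoid response genes by 0.24 and adventitial fibroblast genes by 0.21. Without the Adipoq libraries the differences were 0.168 for smooth muscle, 0.270 for drug metabolism and 0.136 for adventitial genes, and none of these 3 passed (adjusted permutation p = 0.16 each). In series A, with 13 nintedanib and 11 vehicle mice, the lymphatic (-0.240, adjusted permutation p = 0.13), VEGF (-0.127, 0.14), adventitial (0.238, 0.097) and drug metabolism (0.361, 0.13) scores did not pass, with differences near those in all libraries. With median scores the calls of unfolded protein response (0.15), lymphatic (0.15), glucocorticoid (0.13) and adventitial genes (0.69) were lost. With mean z scores those of glucocorticoid (0.085), adventitial (0.090) and drug metabolism genes (0.077) were lost. Pericyte genes, a list that holds Pdgfrb, passed as lower with median scores (-0.327, adjusted permutation p = 0.046). Their main score did not pass (-0.18, adjusted permutation p = 0.076). The collagen score differed by -0.18 with an interval of -0.57 to 0.20 (adjusted permutation p = 0.59), beside a bleomycin change of 1.27 (0.95 to 1.60). The cell cycle score differed by -0.52 (-0.96 to -0.05, adjusted permutation p = 0.11).

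**Figure D5:**
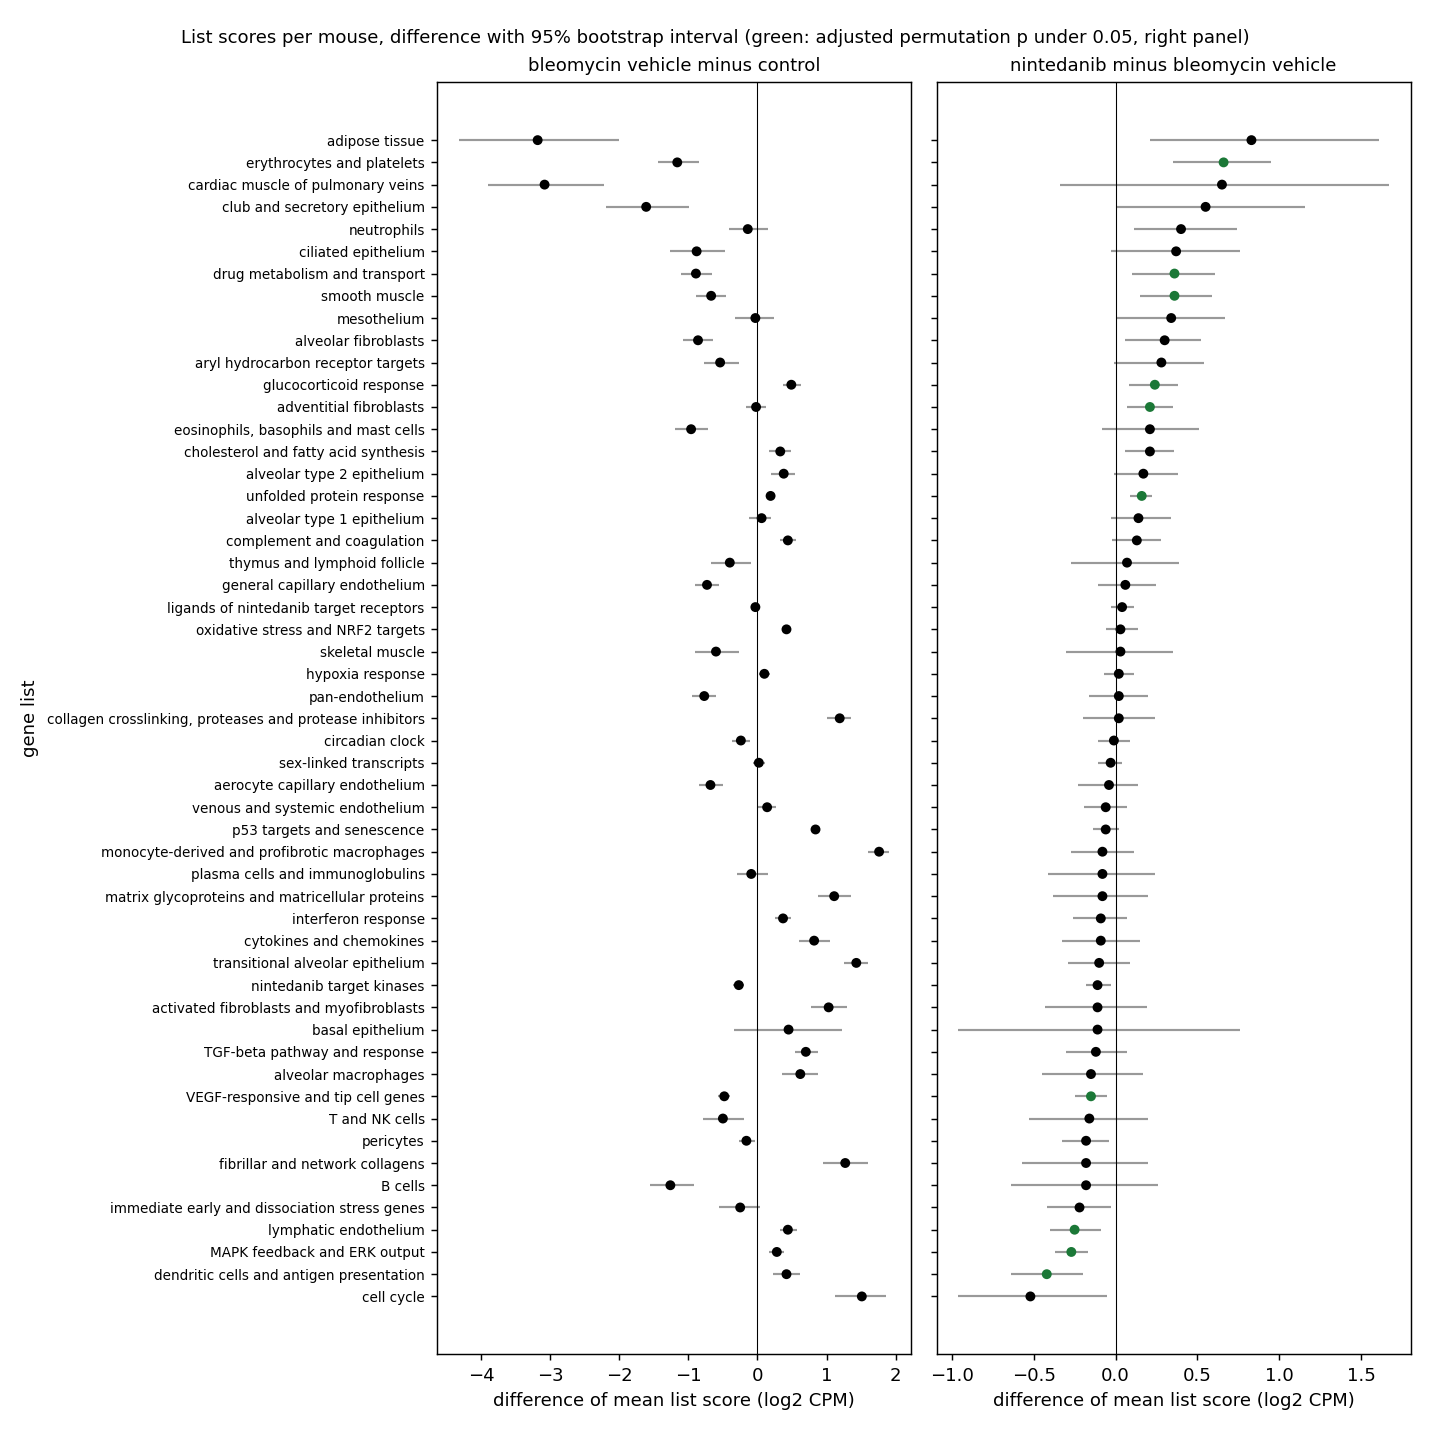
For each gene list the x axis gives the difference of the mean list score (log2 CPM) between groups with its 95% bootstrap interval over mice, on the left bleomycin vehicle minus control and on the right nintedanib minus bleomycin vehicle; green points mark the 10 lists with an adjusted permutation p under 0.05. The collagen list lies at 1.27 on the left and at -0.18 on the right, where its interval includes 0.

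Whether genes changed by bleomycin moved back toward control under nintedanib was measured with the vehicle mice split into 2 sets of 8. The mean slope over 50 splits was -0.161 (range -0.316 to -0.0271), and the mean covariance was -0.122. Resampling mice gave a 95% interval from -0.409 to 0.0874, which includes 0. Without a split the slope was -0.179. A simulated unchanged group gave 0.00456, but it was drawn around the means of the same vehicle libraries, gene by gene. That simulation could therefore show neither the effect of shared libraries nor that of differences between mice. Of the genes called against control with the first set, 336 on average (37 to 1414 over the splits) were also called between nintedanib and the second set, 269 of them (10 to 1342) in the opposite direction, and no such count was made for an unchanged group.

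The third comparison, nintedanib against control, asked how far treated bleomycin lungs remained from control lungs. Profibrotic macrophage, transitional epithelium, and p53 target and senescence genes were higher and VEGF-responsive genes lower. These 4 list calls held with an estimated correlation. The VEGF-responsive list was lower without the drug too. In vehicle against control mice 12 of its 22 members fell and 3 rose (camera adjusted p = 0.0019 and adjusted p = 0.33 with an estimated correlation). Its mean score was 5.45 in control, 4.97 in vehicle and 4.82 in nintedanib mice. Collagens were higher and pan-endothelial genes lower at the preset correlation alone (adjusted p = 0.38 and 0.14 with an estimated correlation). The largest rises belonged to Thbs4, Grem1, Saa3, Slc26a4, Chl1, Sprr1a, Mmp12 and Gpnmb. By edgeR's quasi-likelihood test 7888 genes changed, 4171 upward and 3717 downward, and 1100 at least 2-fold.

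Thbs4 rose by 5.52 ± 0.69 on the log2 scale (adjusted p = 1e-08), Mmp12 by 4.43 ± 0.26 (adjusted p = 2e-17) and Gpnmb by 4.28 ± 0.30 (adjusted p = 6.3e-15). Spp1 was at 4.01, Trem2 at 3.74, Timp1 at 3.34, Cdkn1a at 2.32, Col3a1 at 1.72, Col1a1 at 1.45 and Mki67 at 1.38. Of 18 collagens 17 rose (17 adjusted over the list alone, camera adjusted p = 7.1e-06 and adjusted p = 0.38 with an estimated correlation). Of 24 profibrotic macrophage genes 20 rose (20 higher and 1 lower adjusted over the list alone and adjusted p = 0.011 with an estimated correlation), and of 19 transitional epithelium genes 18 rose (19 adjusted over the list alone and adjusted p = 0.028 with an estimated correlation). Of 22 p53 target and senescence genes 17 rose and 2 fell (17 and 3 adjusted over the list alone and adjusted p = 0.0017 with an estimated correlation).

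Of 22 VEGF-responsive genes 13 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 5.3e-07 and adjusted p = 0.013 with an estimated correlation), with Igfbp3 at -1.90, Apln at -1.70 ± 0.14, Esm1 at -1.37 and Kdr at -1.26 ± 0.11. Of 22 pan-endothelial genes 21 fell (21 adjusted over the list alone, camera adjusted p = 1.1e-13 and adjusted p = 0.14 with an estimated correlation), and Flt4 was at -0.57. Of 15 B cell genes 14 fell (14 adjusted over the list alone, camera adjusted p = 2.6e-07 and adjusted p = 0.34 with an estimated correlation). Among the largest falls were the fat genes Cidea (-4.22), Pck1 and Plin1, and also Bex2 (-3.04) and the chemokine receptor Ackr4 (-2.05). Without the libraries with at least 1 CPM of Adipoq, which leaves 2 control libraries, 3297 genes were called, 3187 of them among the 7888. With library totals alone the split was 3250 upward and 4844 downward, and with only the 2 groups in the fit 3729 and 4482.

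Spread between mice was larger in bleomycin vehicle mice than in control mice for 14 of 54 measures and smaller for 1, the adipose score. With median scores 4 measures differed, 3 of them larger. The SD of the collagen score was 0.673 in vehicle mice and 0.0828 in control mice (ratio 8.13, adjusted permutation p = 0.024), and that of the cell cycle score was 0.760 against 0.0912 (ratio 8.33, adjusted permutation p = 0.024). Between nintedanib and vehicle mice 0 of 54 measures differed in spread by the permutation test, with 7 at an unadjusted p under 0.05. Between nintedanib and control mice 0 of 54 differed, with 18 at an unadjusted p under 0.05, and 3 with median scores.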

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

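The tests of endothelial content, of fat and airway tissue, of a drug effect on fat and of the axis score were chosen only after the result was seen. Among the 10 control mice, 74 values (list scores and log2 CPM of single genes) were tested for a library set apart from the others by Dixon's gap, and 9 gaps were found; chance flags about 1 in 20 groups. Groups of more than 10 mice were not tested this way.

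Control 1 had the highest score of pericyte genes (mean log2 CPM 5.55, nearest 5.41) and of cholesterol and fatty acid synthesis (6.86, nearest 6.45). Control 6 had the lowest score of mesothelial genes (5.50, nearest 5.89) and of alveolar type 2 genes (8.48, nearest 8.70). Control 4 had the highest score of transitional alveolar epithelium (5.14, nearest 4.90) and of ERK feedback genes (5.07, nearest 4.83). Control 9 had the lowest score of cytokines and chemokines (1.48, nearest 1.81), and control 2 the lowest of thymus and lymphoid follicle genes (2.49, nearest 3.10). Control 2 also had the highest log2 CPM of Cyp1a1, 6.38 beside 3.47 in the nearest mouse.

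Fat and airway mucosa transcripts stood in part of the libraries. Fat and large-airway tissue taken along with the lobe is a candidate explanation. Within groups the fat score and Bpifa1 rose together, with Pearson r = 0.577 (one-sided permutation p = 0.00059) and Spearman rho = 0.359 (one-sided permutation p = 0.014). Pearson r was 0.434 without the 2 mice farthest from their group median. All permutation p-values of this relation, also within single groups, are one-sided. Within nintedanib mice r was 0.750 (adjusted p = 0.0017 over 3 groups) but rho 0.490 did not pass (adjusted p = 0.073). Control mice had r = 0.398 (adjusted p = 0.18) and -0.380 without 2 mice. Vehicle mice, none of which reached 1 CPM of Adipoq, had r = 0.0255 (adjusted p = 0.46), and why they showed no relation was not tested. A drug effect that lifts fat above the vehicle range in all mice is argued against. Only 5 of 17 nintedanib mice lay above the highest vehicle mouse in fat score. A smaller shift in all mice stays open. In fat score 14 of 17 nintedanib mice lay above the vehicle median (difference 0.83, 95% interval 0.21 to 1.61). An effect in part of the mice stays open. Of the control mice, given no drug, 8 of 10 held Adipoq, which cannot decide on a drug effect in bleomycin mice. Why no vehicle mouse held fat stays open.

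Genes of the VEGF, ERK and lymphatic lists were lower under nintedanib, 13 members with a median log2 fold change of -0.50. These members were chosen because they fell, so their median cannot set the size of a loss of endothelial cells. As whole lists the scores differed by -0.15 (VEGF), -0.27 (ERK) and -0.25 (lymphatic). Vehicle minus control was -0.48 (VEGF), 0.28 (ERK) and 0.44 (lymphatic). The VEGF score thus moved further from control under nintedanib, and the ERK and lymphatic scores moved toward control. The pan-endothelial score differed by 0.02 with a 95% interval of -0.16 to 0.20. This interval holds the VEGF difference but not the other 2. The pan-endothelial median log2 fold change was 0.02, and -0.04 with 2 surrogate variables. With these variables the pan-endothelial and aerocyte lists were called lower by camera (adjusted p = 0.030 and 0.014). The planned test of normalization decided nothing: all 13 members (share 1) were still called with RLE factors and library totals, but neither scaling moved them toward 0, and a later comparison of these members with the median gene was dropped because their choice fixed its outcome. With the bleomycin axis score as a covariate a share of 0.846 was still called (11 of 13): Trp53i11 went from -0.32 to -0.27 (adjusted p = 0.11) and Pgf from -0.50 to -0.32 (adjusted p = 0.096). As a hypothesis, the kinase inhibitor may act directly on endothelial signalling, which phosphorylated ERK in endothelial cells sorted from such lungs would test. A loss of endothelial cells of the size of the VEGF difference or smaller stays open. So do a loss of a subset and a difference in immediate early genes from tissue handling.

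Bleomycin-changed genes were shifted toward control under nintedanib, with a mean slope of -0.161. Vehicle libraries shared by both comparisons are argued against as the cause, since no library stood on both sides of a split. Without the libraries with fat, which leaves out 8 of 10 control and 5 nintedanib mice, the slope was -0.0564 (range -0.17 to 0.0122, below 0 in 18 of 20 splits), a ratio of 0.35 to the slope with them, so a part played by those libraries stays open. Mice that differed by chance in the extent of the response may also explain the shift: the axis score was 1.07 ± 0.293 (SD, n = 16) under vehicle and 0.930 ± 0.255 (n = 17) under nintedanib (permutation p = 0.14).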

How the results depend on the processing

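The fits without the libraries with at least 1 CPM of Adipoq and the fits with fat and airway scores or the bleomycin axis score as covariates were chosen only after the result was seen. A fold change of at least 2 left 1493 genes for bleomycin against control, 71 for nintedanib against vehicle and 1100 for nintedanib against control. Without the Adipoq libraries the counts were 3654, 525 and 3297, with 2 control libraries left. For nintedanib against vehicle voom with quality weights gave 2281 genes (993 shared with the 1084) and a fit of the 2 groups alone 640 (627 shared). The main fit took 1 estimate of spread from all 43 libraries, control mice included. Spread was larger in vehicle than in control mice for 14 of 54 measures, or 3 with median scores. A shared spread can be too small for the bleomycin groups, and the cause of the differing counts was not tested. Leave-one-out over 33 bleomycin libraries gave 696 to 1559 genes, lowest without nintedanib mouse 1, and 589 genes were called each time. Other alternatives for gene counts stayed within 1.5 times. With an estimated correlation camera called 3, 0 and 4 lists, and fry called 9 for nintedanib against vehicle. In series A alone 6 list scores differed; those of VEGF (-0.127), lymphatic (-0.240), adventitial (0.238) and drug metabolism genes (0.361) no longer passed, with differences near those in all libraries (-0.149, -0.247, 0.206 and 0.358).

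Some of the named genes called lost the call, with the direction kept, in at least 1 alternative. These were 64 of 203 (bleomycin against control), 67 of 97 (nintedanib against vehicle) and 80 of 200 (nintedanib against control). Named genes that reversed in any alternative were counted apart, 10, 4 and 3 in the same order. The leave-one-out fits and the 2-fold threshold were not part of these counts. Directions reversed mostly for fat and airway genes. For nintedanib against vehicle, Bpifb1 (-0.38) and Krt15 (-1.76) reversed without the Adipoq libraries, and Krt15 (-1.16), Scgb3a1 (-0.11) and Tpsb2 (0.00) with the fat and airway covariates. For nintedanib against control, Elovl6 was at 0.40 with DESeq2, 0.11 with voom, 0.53 without the Adipoq libraries and 0.75 with the covariates, Plin1 at 0.79 without the Adipoq libraries and Cidea at 0.03 with the covariates. For bleomycin against control, 2 surrogate variables gave Rgs5 0.00 and Postn -0.25, and Elovl6 was at 0.22 with DESeq2 and 0.06 with voom. Without the Adipoq libraries this comparison gave Elovl6 0.59, Pdk4 0.10, Muc5b 1.24, Scgb3a1 1.52, Plin1 1.94 and Bpifa1 0.91. With the covariates it gave Cd1d1 0.01, Elovl6 0.81, Pdk4 0.08, Tpsb2 0.98, Muc5b 0.28, Scgb3a1 0.77, Plin1 0.94 and Bpifa1 1.01.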

Other observations

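The comparison of the cell cycle slope with the p53 and epithelial slope was chosen only after the result was seen. Glucocorticoid response genes were higher under nintedanib than under vehicle as a score per mouse (0.24, 95% interval 0.08 to 0.38, adjusted permutation p = 0.042, 16 of 17 mice). Camera gave an adjusted p of 0.055, and with an estimated correlation it called 0 of 53 lists in this comparison. The score difference was 0.23 as a median over members (adjusted permutation p = 0.13) and mean z scores did not pass (adjusted permutation p = 0.085). It was 0.317 in series A (adjusted permutation p = 0.0025) and 0.266 without the Adipoq libraries (adjusted permutation p = 0.043), where camera also called the list higher (adjusted p = 0.0089 and 0.011), as it did with 2 surrogate variables (adjusted p = 0.0099). Zbtb16 rose by 1.60 ± 0.31 on the log2 scale (adjusted p = 0.0013, 16 of 17 mice) and Fkbp5 (chromosome 17, 28399094 to 28517527) by 0.73 ± 0.18 (adjusted p = 0.011, 16 of 17 mice), and 3 of 14 members were higher and 1 lower adjusted over the list alone. The score of these genes was also higher in vehicle mice than in control mice, by 0.49.

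Of 14 neutrophil genes 4 rose under nintedanib: S100a9, Mmp9 (0.99), S100a8 (0.97) and Csf3r (0.75) passed over all genes and 8 adjusted over the list alone (camera adjusted p = 0.0018 and adjusted p = 0.46 with an estimated correlation). Neither the score per mouse (adjusted permutation p = 0.051) nor fry (adjusted p = 0.071) passed. As mean z scores the neutrophil score passed (adjusted permutation p = 0.027), and as a median over members it did not (adjusted permutation p = 0.22). Of 23 genes of cholesterol and fatty acid synthesis 2 rose, Scd1 (0.60) and Scd2 (0.21), and 3 adjusted over the list alone (camera adjusted p = 1e-05 and adjusted p = 0.46 with an estimated correlation). Each of the 43 libraries held the Y-linked transcript Ddx3y, between 58.8 and 105 CPM.

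Under nintedanib the slope toward control, fitted through the origin over all 27 tested members, was -0.361 for cell cycle genes (95% bootstrap interval -0.943 to 0.128). For the genes of the p53 target and senescence list and of the transitional epithelium list it was -0.0629 (-0.212 to 0.118). Both intervals include 0. Each resample, also for the difference below, took 1 new split, so the intervals hold the spread between splits as well. The slope measures the share of the bleomycin change that moved back, not the remaining distance to control. A milder bleomycin response that scales all gene groups alike would give equal slopes, and the difference was -0.299 (95% bootstrap interval -0.813 to 0.0275). The interval condition of this test was added after the slopes were seen. A separate effect on proliferation may be present, and the interval leaves both readings open; counts of dividing cells in tissue sections of the same mice would test it.

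Chance was tested with 100 splits of the libraries for each comparison, the real split included, and only 1 split, the real one, reached the real count in each. For bleomycin against control the real count was 8585 and the highest other 2005. For nintedanib against vehicle they were 1084 and 779, and for nintedanib against control 7888 and 51. A share of 1 in 100 is the smallest that 100 splits can give. For nintedanib against vehicle the split with 779 calls shows that mice grouped without regard to the drug can differ in many genes. The test covers the counts alone, not single genes or the shift toward control.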
